A study of Rattus norvegicus with 9 samples.

How the data were processed

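Poly(A)-selected RNA from cultured rat microglia was sequenced in 9 libraries, 3 each from cultures given vehicle, lipopolysaccharide (LPS), or LPS followed by an argon gas mixture. The values used were whole-number read counts per gene, deposited by the authors as 1 table for the series without normalization. Per the submitters' processing notes, fastp 0.22.0, HISAT2 2.1.0 and featureCounts were used and the genome build was Rnor_6.0. The order and settings of these tools, the annotation release, the handling of strand and the treatment of reads that map to several places are not given in the sources used here. Counts of genes with near-identical copies, of overlapping genes and of antisense pairs are therefore uncertain. Each column of the table was assigned to its library by the column name that the labels give for that sample, and no column was left over.

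The table held 30562 Ensembl rat gene identifiers, of which 8985 had 0 reads in all 9 libraries. It did not pair identifiers with gene names. The reference gene table used for names held an Ensembl identifier for 0 of its genes and matched 0 of the 30562 identifiers, so genes are given by identifier and no coordinates are printed. For the same reason the 28 pathway lists and 9 cell type marker lists fixed before the data were examined could not be tested, and a fixed panel of inflammatory and microglial genes could not be read out.

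Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with edgeR's filter on low counts, which requires a count of about 10 in the smallest group and a total of 15, leaving 14463 genes. Library composition was scaled by the trimmed mean of M-values (TMM), which sets factors so that the middle of the fold change distribution lies near 0. All 9 libraries entered 1 negative binomial model with a mean per group and 6 residual degrees of freedom. The 3 pairwise comparisons were tested with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over the 14463 genes of each comparison. A gene was called at an adjusted p under 0.05, with no minimum fold change. Standard errors of log2 fold changes were obtained from the fitted fold change and its F statistic. Levels are given as TMM-scaled CPM, the count of a gene relative to the scaled total of its library, computed from the deposited counts. Principal components were taken from log2 CPM with a prior count of 2. Whole-library measures were compared by exact two-sided permutation tests, for which 0.1 is the smallest p that 3 against 3 libraries can give.

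Genes were named by a rule fixed before the data were examined. It takes genes with the largest rise or fall among those called, with a mean of at least 5 CPM in at least 1 of both groups and with no overlap between the libraries of both groups. The rule also required a gene symbol, and this part could not be applied. Because no identifier could be named, 2 genes that rose and 2 that fell are given, all taken from the comparison of LPS plus argon with LPS. Other parts of the rule, for list members, for the panel and for genes changed by both treatments, were not run.

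The groups share replicate numbers, so pairing was checked from each gene's deviation from its group mean in log2 CPM. Across genes, deviations of libraries with the same number correlated at 0.591 to 0.612 for number 1, 0.473 to 0.523 for number 2 and 0.72 to 0.738 for number 3. All of these exceeded the limit of 0.1 set for treating numbers as pairs, and the pairing comes from the data and not from the labels. Deviations sum to 0 within a group, however, so the strong deviation of replicate 3 makes replicates 1 and 2 deviate together. Number 3 correlated with numbers 1 or 2 of other groups at -0.679 to -0.583, and numbers 1 and 2 correlated across groups at 0.509 to 0.56. Passing the limit therefore does not show that numbers 1 and 2 form separate pairs. Only libraries numbered 1 and 3, which are 6 of the 9, correlated best with their own number. A model with the replicate number as a block, with 4 residual degrees of freedom, was the fixed alternative, and its values are given where they move a count by over 1.5 times. Replicates 1 and 2 of each group differed by 3.02 to 4.01 in chi-square per gene against 1 for pure counting noise, over genes with at least 20 reads in the pair. Pairs with replicate 3 differed by 45.7 to 79.7. Replicates 1 and 2 were counted separately because the labels describe them as independent and they were not identical within counting noise, which separately prepared libraries of 1 culture would also exceed. If they came from 1 preparation, p-values would measure in part a technical spread.

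The other alternatives were size factors by the DESeq2 method, scaling by library size only, no filter on low counts, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, voom in limma 3.58.1, fits on the 6 libraries of a comparison, an adjusted p of 0.01, and leaving out each library in turn. A fit on replicates 1 and 2 only was added after the data were seen, as was a division that takes the size of the LPS response from replicate 3, in log2 CPM, and argon calls from replicates 1 and 2. Both LPS comparisons with a common group share libraries, so expected correlations and overlaps were taken from 100 simulated data sets per setting with libraries that varied independently, and, added after the data were seen, from 50 that kept the replicate effects and spread of the blocked model. The setting with an LPS effect and no argon effect gave LPS and LPS plus argon their common mean. Its LPS effect is therefore averaged over both groups. The procedure was tested on simulated counts drawn from the real library sizes and gene means, with 10 draws per comparison over 14463 genes. Over the 10 draws of a comparison, 670 genes were changed by 1.5-fold, 670 by 2-fold and 660 by 4-fold. These are far fewer than were called in the real data. The simulated libraries also varied independently, with the spread of the model without a block. In the real data replicate 3 deviates in the same genes in all groups. The recovery and the share of false calls therefore do not carry over to the real data directly. Genes changed by 4-fold were recovered in 75.9% of cases for LPS against vehicle, 77.7% for LPS plus argon against LPS and 73.6% for LPS plus argon against vehicle. The corresponding shares were 42.4%, 40.7% and 43.3% for 2-fold changes and 5.37%, 5.97% and 6.57% for 1.5-fold changes. False calls made up 6.06%, 5.38% and 6.29% of calls. The number of draws was raised to 10 after a smaller run had exceeded the limit set for false calls.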

Results

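Gene expression was measured by RNA sequencing in primary microglia, the resident immune cells of the brain, cultured from fetal Sprague-Dawley rats. Cultures were given vehicle or 100 ng/mL LPS, a bacterial cell wall component that activates innate immune receptors, and RNA was collected after 4 h. A further set received LPS and then 3 h in a gas mixture of 74% argon, 21% oxygen and 5% carbon dioxide. Argon is a noble gas that replaces the nitrogen of air in this mixture. The gas over the vehicle and LPS cultures is not given in the sources used here, so a change between LPS and LPS plus argon is a change with the whole gas exposure. Each of the 3 groups had 3 libraries, which the labels describe as independent biological replicates. Total counts per library ranged from 18930745 to 22604955, and 14463 genes had enough reads to be tested.

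Fewer genes were detected in LPS cultures than in vehicle cultures, and the most abundant genes took a larger share of their counts. The 500 most abundant genes of a library held 49.2% ± 0.909 (SD, n = 3) of counts with vehicle, 57.5% ± 1.2 with LPS and 56.9% ± 1.25 with LPS plus argon. Genes with at least 1 read numbered 18333 ± 264 with vehicle, 17577 ± 316 with LPS and 18124 ± 233 with LPS plus argon. Both measures separated the vehicle and LPS libraries without overlap, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give. The number of detected genes also separated LPS plus argon from LPS without overlap (exact p = 0.1), whereas the share of the 500 most abundant genes did not (exact p = 0.5). This permutation test ignores replicate numbers, and replicate 3 had the highest share in both groups. Between libraries of equal number the share was slightly lower with argon each time. In order of replicate number it was 56.1% against 56.7%, 56.3% against 57.0% and 58.4% against 58.9%. In a principal component analysis, the first component carried 54.6% of the variance and set vehicle libraries apart from both LPS-treated groups. In every group, replicate 3 lay apart from replicates 1 and 2 on the second component, which carried 23.5% of the variance. With the groups accounted for, 3852 genes differed between replicates 3 and 1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Between replicates 2 and 1 this test called 0 genes, and 244 had an unadjusted p under 0.05. The spread of this fit includes the replicate 3 libraries, with a common biological coefficient of variation of 0.112 against 0.0436 for replicates 1 and 2 only. The 0 therefore does not show that replicates 1 and 2 are alike.

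**Figure D1:**
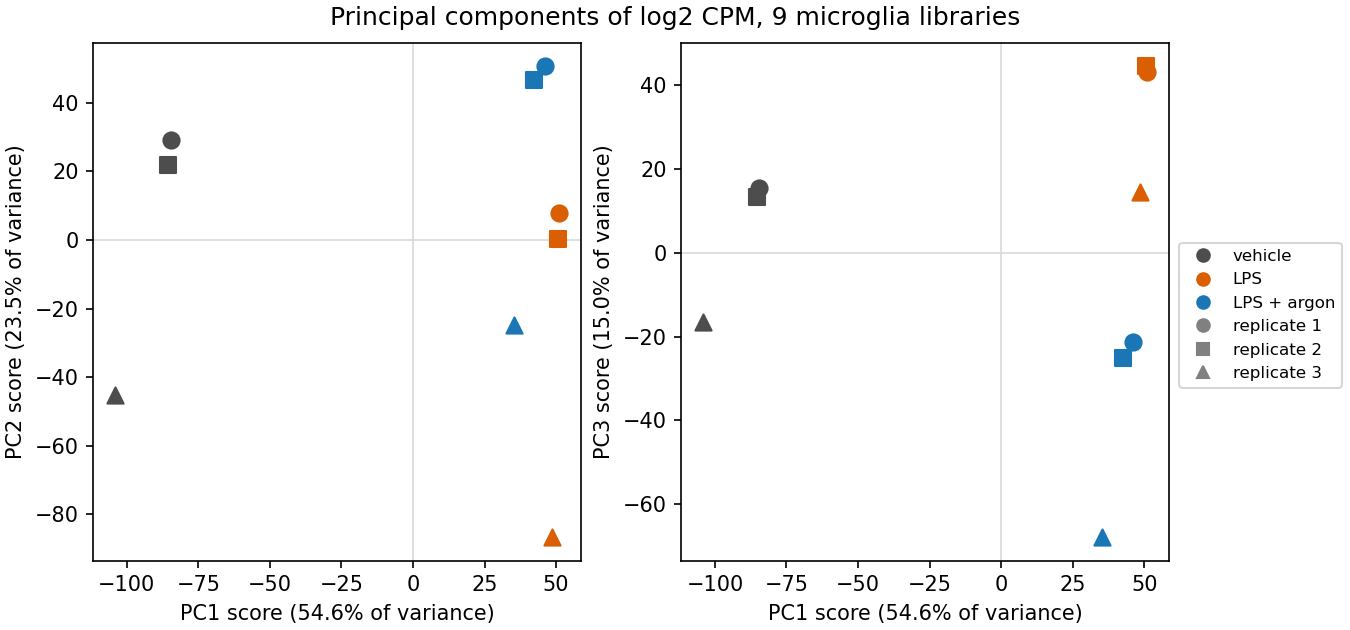
Scores of the 9 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM, with the percent of variance on each axis; colours mark groups and symbols mark replicate numbers. Vehicle libraries lie at negative scores on component 1 and all LPS-treated libraries at positive scores, and replicate 3 has the lowest score of its group on components 2 and 3.

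The comparison of LPS with vehicle asked how microglia respond to the bacterial stimulus. LPS changed 7260 of the 14463 genes tested (50.2%), of which 3227 rose and 4033 fell. Among called genes, the median log2 fold change was 1.14 for those that rose and -0.96 for those that fell, and changes over 2-fold were found for 1791 rising and 1906 falling genes. Rises were concentrated in abundant genes. Of the 1303 called genes with a mean over 100 CPM in all libraries, 1116 rose, whereas 1604 of the 2077 called genes with a mean of 1 to 10 CPM fell. The LPS-treated libraries are 6 of the 9 behind that mean, so a strong rise itself places a gene in a higher class. A set of 32 genes was switched from under 0.5 CPM in every vehicle library to at least 5 CPM in every LPS library. ENSRNOG00000067968 rose from 0.667 ± 0.385 CPM (SD, n = 3) with vehicle to 88.3 ± 33.6 CPM with LPS, a log2 fold change of 7.04 (SE 0.59), and ENSRNOG00000018915 rose from 1.46 ± 0.57 to 11.9 ± 8.94 CPM, a log2 fold change of 3.02 (SE 0.77). The adjusted p was 1.97e-05 for the first and 0.0103 for ENSRNOG00000018915 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and limma-voom gave 0.0867 for the latter. Both genes were chosen for their fall from LPS to LPS plus argon, which favours high LPS libraries, so their rise carries a selection effect. For ENSRNOG00000018915, LPS replicate 3 (1.66 CPM) lay within the vehicle range of 0.838 to 1.96 CPM. When libraries were scaled by their totals alone, the median of all genes moved from -0.04 to -0.68 in log2 and 8096 of 9760 called genes fell (83% against 55.6%), so directions are relative to the middle of the tested genes. Under that scaling 639 of the 1400 called genes over 100 CPM rose and 2756 of the 3024 at 1 to 10 CPM fell, and changes over 2-fold were found for 1085 rising and 4752 falling genes.

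The comparison of LPS plus argon with LPS asked what the gas exposure changed in stimulated cells. It changed 4327 genes (29.9%), of which 1592 rose and 2735 fell, with median log2 fold changes of 0.78 and -0.82. Changes over 2-fold were found for 536 rising and 1014 falling genes. The fall was most common among abundant genes, where 577 of the 763 called genes over 100 CPM were lower with argon, against 541 of 1025 at 1 to 10 CPM. With scaling by library totals the balance over 2-fold turned, to 846 rising and 683 falling genes. Of the genes not called for LPS, argon raised 436 (285 without LPS replicate 2) and lowered 766 (422 with scaling by library totals).

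Among genes that passed the naming rule, the largest rise was in ENSRNOG00000043465, which stood at 1.07 ± 0.295 CPM with vehicle, 1.24 ± 0.307 with LPS and 74.0 ± 75.5 with LPS plus argon (SD, n = 3). Its log2 fold change with argon was 5.90 (SE 0.79). The size rests partly on replicate 3, with 161 CPM against 29.8 and 31.1 in the others, and was 4.61 without that library. ENSRNOG00000001728 rose from 13.3 ± 2.72 CPM with LPS to 417 ± 239 CPM with argon, a log2 fold change of 4.97 (SE 0.40), against 7.92 ± 0.122 CPM with vehicle. Here too LPS plus argon replicate 3 was highest, at 692 CPM against 260 and 300, and the log2 fold change was 4.39 without that library. Between LPS and vehicle, ENSRNOG00000043465 was not called, and ENSRNOG00000001728 was not called (adjusted p = 0.119, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) except in the fits on the 6 libraries of the comparison (adjusted p = 0.0113), on replicates 1 and 2 (adjusted p = 2.02e-07) and without LPS plus argon replicate 3 (adjusted p = 0.00384). Over all settings and tools its adjusted p for this comparison ranged from 2.02e-07 to 0.789. The lowest came from replicates 1 and 2 alone, whose spread may be in part technical. The largest falls were in ENSRNOG00000018915, to 0.197 ± 0.119 CPM (log2 fold change -5.84, SE 0.99), and ENSRNOG00000067968, to 1.75 ± 1.03 CPM (log2 fold change -5.64, SE 0.55). Both had been raised by LPS, and ENSRNOG00000018915 reached 15.6 and 18.3 CPM in LPS replicates 1 and 2 but 1.66 CPM in replicate 3. In LPS plus argon its raw counts were 5, 5 and 1. Adjusted p-values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.000789, 7.4e-05, 0.00254 and 0.000175 in the order given, and limma-voom did not call ENSRNOG00000018915 (adjusted p = 0.125).

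**Figure D2:**
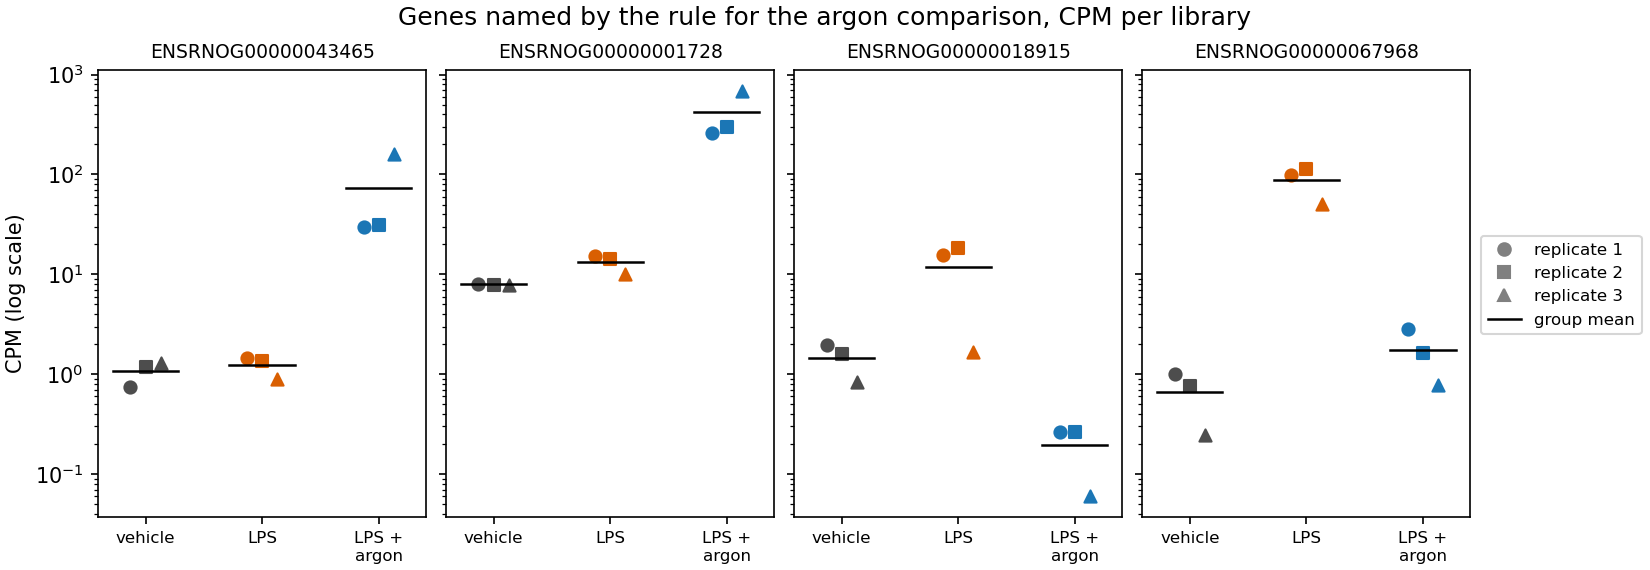
CPM on a log axis in each library for the 4 genes named by the rule, by group; symbols are replicates and horizontal lines are group means of 3 libraries. ENSRNOG00000043465 and ENSRNOG00000001728 are highest in the LPS plus argon libraries (means 74.0 and 417 CPM), and ENSRNOG00000018915 and ENSRNOG00000067968 are highest with LPS (means 11.9 and 88.3 CPM).

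The number of genes changed by argon depended on how replicate 3 was handled. With the replicate number as a block, 6797 genes were called, 3264 higher and 3533 lower (52% lower against 63.2%). With replicates 1 and 2 alone 7730 were called, a setting chosen after the data were seen. If these replicates came from 1 preparation, the p-values of that fit would measure in part a technical spread, and its count would be too high. The block added mainly rises, with 851 against 536 genes higher by over 2-fold and 1099 against 436 genes higher among those not called for LPS. At 1 to 10 CPM the balance turned, as 710 of 1978 called genes were lower with the block (35.9%), 739 of 2032 with replicates 1 and 2 (36.4%) and 400 of 1167 with scaling by library totals (34.3%). Scaling by library totals alone moved the median of all genes from 0.05 to 0.23 in log2 and turned the balance, with 2664 genes higher and 1969 lower (42.5% lower), including 391 higher and 410 lower over 100 CPM.

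**Figure D3:**
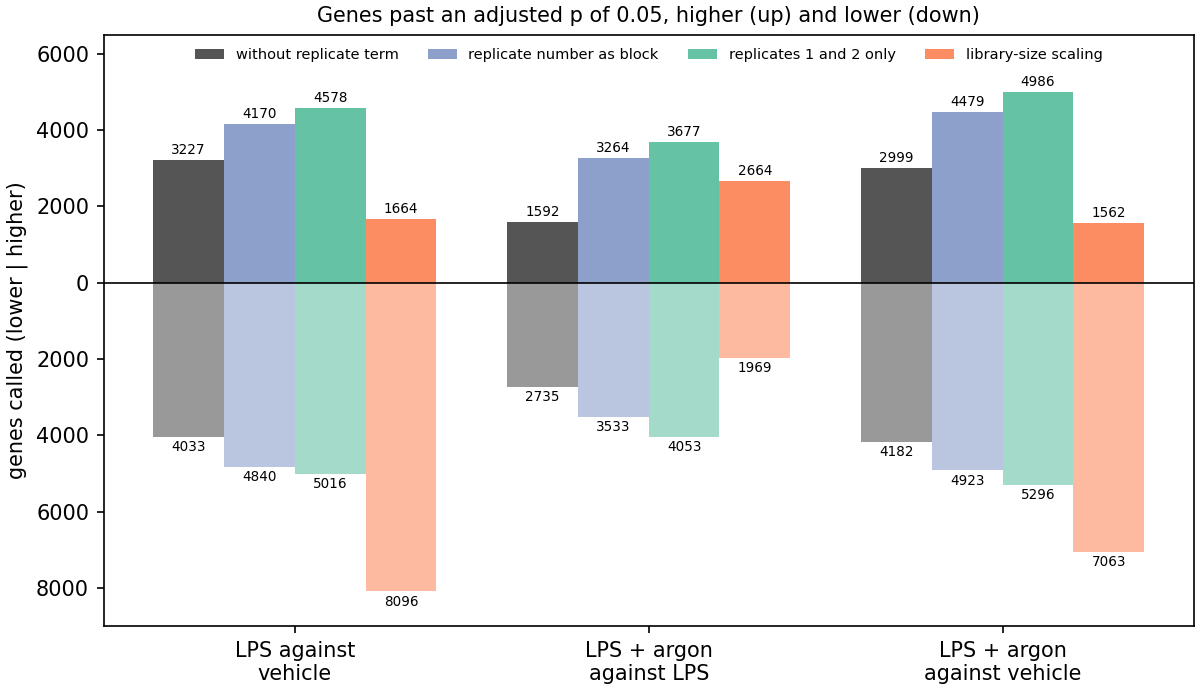
Number of genes past an adjusted p of 0.05 that were higher (above 0) or lower (below 0) in each of the 3 comparisons, without a replicate term, with the replicate number as a block, with replicates 1 and 2 only and with library-size scaling. The count for LPS plus argon against LPS is 4327 without and 6797 with the block.

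The comparison of LPS plus argon with vehicle asked how far exposed cells remained from the unstimulated state. It gave 7181 called genes, 2999 higher and 4182 lower, close in number to the 7260 called for LPS alone. Of the 3227 genes raised by LPS, 2153 (66.7%) were also called higher with LPS plus argon, and of the 4033 lowered by LPS, 2953 (73.2%) were also called lower. Independent lists of these sizes would share 669 and 1166 genes. In simulations with an LPS effect averaged over both LPS-treated groups and no argon effect, 5542 genes were shared in the same direction on average. The count was 5708 when the simulated libraries also kept the replicate effects, against 5106 observed. Both comparisons use the same vehicle libraries, so these can account for part of the overlap. Calls in opposite directions were found for 173 genes that were higher with LPS and lower with LPS plus argon, and for 28 genes that went the other way (287 and 87 with the replicate block). These were 109 and 8 without vehicle replicate 1 and 106 and 10 without vehicle replicate 2, and the 28 became 18 with no filter on low counts and 58 with scaling by library totals. Of the 32 genes switched on by LPS, 16 were also at 5 CPM or more in every LPS plus argon library, and 0 were back under 0.5 CPM in every such library. ENSRNOG00000067968 was at 1.75 ± 1.03 CPM (SD, n = 3) with LPS plus argon against 0.667 ± 0.385 with vehicle, a difference that did not pass the test (log2 fold change 1.40, SE 0.61; adjusted p = 0.0871, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and passed it with the replicate block (adjusted p = 0.00237). Across genes, the log2 fold changes of both LPS-treated groups against vehicle correlated at 0.82. The value was 0.482 in simulations of the same shared vehicle libraries with no treatment effect and 0.954 in those with the averaged LPS effect alone. The observed covariance was 1.35, against 0.0726 and 1.66 in these simulations, or 0.0237 and 1.52 with the replicate effects kept. With the LPS effect from replicate 3 and the effect of LPS plus argon from replicates 1 and 2, so that no library was shared, the correlation was 0.744, and with the replicates exchanged it was 0.746, a division chosen after the data were seen. With scaling by library totals the median of all genes moved from -0.01 to -0.47 in log2 and 7063 of 8625 called genes were lower (81.9% against 58.2%). Under that scaling 1126 genes were higher and 6324 were lower in both LPS-treated groups than with vehicle, against 2153 and 2953.

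The position of each LPS-changed gene after argon was then examined. Argon lowered 1506 of the 3227 genes that LPS had raised (46.7%) and raised 961 of the 4033 that LPS had lowered (23.8%), so that 2467 genes moved back. The 961 became 640 without LPS plus argon replicate 2. Independent lists of these sizes would share 610 and 444 genes, a value that leaves out the LPS libraries common to both comparisons. In simulations with these libraries shared, an LPS effect averaged over both LPS-treated groups and no argon effect, 0.05 genes were called in opposite directions and 0.02 in the same direction on average, a value that leaves out the argon effects. Movement further in the LPS direction was less frequent, with 195 genes raised by both and 463 lowered by both, where independent lists would give 355 and 763. The 195 became 123 without LPS replicate 1 and 121 without LPS replicate 2, and the 463 became 304 without LPS replicate 2 and 287 in the fits on 6 libraries. With the replicate block these were 592 and 698 genes, where independent lists would give 941 and 1182, and 1573 LPS-lowered genes moved back against 961. Of the 1506 genes that argon lowered, 730 were still above vehicle, 603 were not called against vehicle and 173 had fallen below it. Of the 961 that argon raised, 477 were still below vehicle, 456 were not called and 28 had passed above it. With the block, 287 and 87 genes had passed vehicle, and 803 of the LPS-lowered genes moved back were still below it. The 477 became 302 without LPS plus argon replicate 1 and 271 without LPS plus argon replicate 2, and the 456 became 298 in the fits on 6 libraries. With scaling by library totals, 361 of the LPS-raised genes moved back were still above vehicle and 295 were not called, and 1365 of the LPS-lowered genes were still below it and 711 were not called. The median log2 fold change against vehicle of the 1506 genes was 1.24 with LPS and 0.33 with LPS plus argon, and that of the 961 genes was -1.12 and -0.37. The genes were chosen by these same tests, so the medians carry a selection effect.

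The share moved back was then taken by the size of the LPS response. The LPS libraries set the size and also enter the comparison with argon, so a chance deviation in them places a gene in a higher class and moves it back as well. Among genes lowered by LPS it was 18.6% of 2127 genes changed less than 2-fold, 27% of 1517 genes changed 2- to 4-fold, 39.9% of 366 genes changed 4- to 16-fold and 43.5% of 23 genes changed over 16-fold. Among genes raised by LPS it was 41.8% of 1436 genes under 2-fold, 52.9% of 913 genes at 2- to 4-fold, 50% of 656 genes at 4- to 16-fold and 42.8% of 222 genes over 16-fold. Movement further in the LPS direction was found for 15.1%, 8.44%, 3.55% and 0% of the lowered classes in this order. For the raised classes it was 4.32%, 6.13%, 8.84% and 8.56%. The genes raised over 16-fold had a median log2 fold change of 5.52 with LPS and 4.71 with LPS plus argon against vehicle. No test was run of the differences between these classes. The order among LPS-raised genes depended on the setting, as the shares moved back under 2-fold and over 16-fold were 51.8% and 36% with scaling by library totals, 40.6% and 58.1% with the replicate block, and 43.9% and 64.2% with replicates 1 and 2 alone. In a division chosen after the data were seen, so that no library was shared, size was taken from replicate 3 for all tested genes and argon calls from replicates 1 and 2. Of genes lower with LPS in replicate 3, 26.8% of 5197 under 2-fold, 36.9% of 2054 at 2- to 4-fold and 42.5% of 539 at 4- to 16-fold were called higher with argon. Of genes higher with LPS in replicate 3, 35% of 4400 under 2-fold, 52.6% of 1214 at 2- to 4-fold, 62.1% of 710 at 4- to 16-fold and 69.6% of 250 over 16-fold were called lower with argon. Argon calls in the LPS direction were found for 19.2%, 10.4% and 6.49% of these lowered classes. For the raised classes they were 19.8%, 16%, 18.2% and 18.8%, so the lowered genes under 2-fold were the closest to balance. With size and LPS calls from replicates 1 and 2, the argon difference in replicate 3 had the opposite sign for 57.8%, 67.9% and 79.1% of the lowered genes and for 59.5%, 71.9%, 74.3% and 72.9% of the raised genes in the same order of classes.

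Across all 14463 genes, the log2 fold changes of LPS against vehicle and of argon against LPS correlated at -0.357 (Pearson), where genes are not independent replicates. Both comparisons contain the LPS libraries, which alone gives a negative value. In 100 simulations each, the correlation was -0.155 on average with an LPS effect averaged over both LPS-treated groups and no argon effect, and -0.513 with no effect of either treatment, where chance values make up all of the spread. The covariance, to which shared libraries add about the same amount in both settings, was -0.361, against -0.0821 and -0.0788. These simulated libraries varied independently. In 50 simulations each that kept the replicate effects and the spread of the blocked fit, the correlation was -0.103 and -0.539 and the covariance was -0.0319 and -0.0308 in the same order. When the LPS effect was taken from replicate 3 and the argon effect from replicates 1 and 2, so that no library was shared, the correlation was -0.311, and with the replicates exchanged it was -0.318. With scaling by library totals, 2919 genes moved back, 785 of 1664 LPS-raised genes (47.2%) and 2134 of 8096 LPS-lowered genes (26.4%), and 1746 of them were among the 2467.

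**Figure D4:**
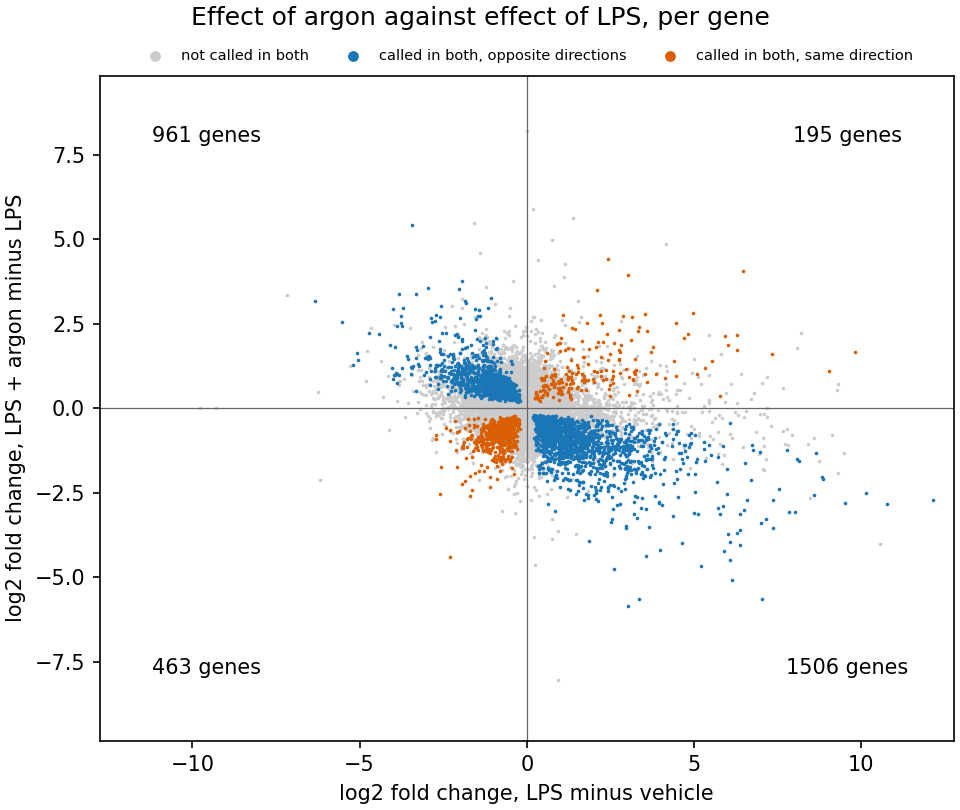
Log2 fold change of LPS plus argon against LPS (vertical) plotted against that of LPS against vehicle (horizontal) for each tested gene; blue genes were called in both comparisons in opposite directions, orange genes in the same direction, and grey genes were not called in both. The corner numbers count the coloured genes, with 1506 and 961 in opposite and 195 and 463 in the same directions.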

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

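The fit on replicates 1 and 2 and all alternatives for both correlations were chosen after the results were seen; the others were fixed beforehand. Of 116 recomputed counts and correlations, 106 lay within 1.5 times the count or within the spread between replicate numbers, and 10 did not. Among 57 recomputed counts of called genes, the majority direction turned in 2, to 3588 higher and 3567 lower for LPS against vehicle with DESeq2 and to 2664 and 1969 for argon against LPS by library size. Genes called for argon against LPS numbered 6797 with the replicate block, 7730 with replicates 1 and 2 only and 2509 at an adjusted p of 0.01, against 4327. The common biological coefficient of variation was 0.243 over all libraries, 0.112 with the block and 0.0436 with replicates 1 and 2 only. The last value would be in part a technical spread if both came from 1 preparation. Genes moved back numbered 4083 with replicates 1 and 2 and 1431 at a p of 0.01, against 2467. With the block, genes moved back numbered 3596, genes called for LPS against vehicle 9010 and for LPS plus argon against vehicle 9402. Leaving out each library in turn gave 6270 to 7662 genes for LPS against vehicle, 3195 to 4358 for argon against LPS, 6082 to 7860 for LPS plus argon against vehicle, 1835 to 2476 moved back, 425 to 648 moved further in the LPS direction and correlations of -0.392 to -0.321 between LPS and argon effects and 0.784 to 0.824 between both effects against vehicle. The latter was 0.82 and became 0.672 with no filter and 0.699 with DESeq2, both over 21577 genes (0.82 and 0.819 over the 14463), and 0.744 and 0.746 from separate, fewer libraries. With library-size scaling, 335 of the 9760 genes called for LPS against vehicle had the opposite direction under TMM. For the 4 named genes, 197 of 216 recomputed values kept direction and side of the threshold, 10 lost the call, 7 gained it and 2 changed sign. Both changes of sign were in ENSRNOG00000043465 for LPS against vehicle, not called in any setting, which went from 0.20 to -0.43 with library-size scaling and ranged from -0.012 to 0.39 on leaving out libraries (lowest without vehicle replicate 1). ENSRNOG00000018915 lost the call in all 3 comparisons with limma-voom and, for LPS plus argon against vehicle, on leaving out LPS replicate 1 or any vehicle or LPS plus argon library (log2 fold change -3.10 to -2.43), where adjusted p over the 9 fits ranged from 0.00181 to 0.121 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment); the cause was not tested. The block, DESeq2 and replicates 1 and 2 only gained the call of ENSRNOG00000067968 for LPS plus argon against vehicle, and the block changed no other call of a named gene. Leaving out LPS plus argon replicate 3 also gained it (adjusted p = 0.043) and gained ENSRNOG00000001728 for LPS against vehicle (log2 fold change 0.75, adjusted p = 0.00384), which the fits on 6 libraries and on replicates 1 and 2 also called. The gene list tests and their alternatives were not run, since no identifier matched a name. Few 1.5-fold changes were recovered in simulated counts, where few genes changed. All 10 draws together gave 873 calls for argon against LPS, against 4327 in the real comparison. That recovery is therefore not a measure for the real data, where the lower quartile of called rises with argon was 0.54 in log2, under 1.5-fold.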

Other observations

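The tests of a shared culture or preparation set and of a uniformly weaker LPS response were chosen after the result was seen, as were the fits on separate libraries and on replicates 1 and 2. The genes that 2 replicates called for argon against LPS moved the same way in the remaining replicate in most cases, as 7189 of the 7730 genes called from replicates 1 and 2 had the same sign in replicate 3 (93%).

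Argon effects opposed LPS effects for 2467 genes and went with them for 658, against 3596 and 1290 with the replicate block (a ratio of 2.79) and 4083 and 1769 with replicates 1 and 2 (2.31). The LPS libraries common to both comparisons do not account for this alone, because with separate libraries the weaker correlation was still -0.311. Opposite calls were at least 3.11 times as many as calls in the same direction under all 3 scalings (2919 against 940 with library-size scaling). This ratio cannot exclude composition scaling, because an offset in the LPS libraries shifts both comparisons in opposite directions and adds opposite calls. With library-size scaling 2134 of the 2919 were LPS-lowered genes that argon raised, against 961 of 2467. A shift common to all genes would leave the correlation nearly unchanged. It was -0.357 with TMM, -0.358 with size factors by the DESeq2 method and -0.352 with library-size scaling. Such a shift alone therefore does not give the negative value. A uniformly weaker LPS response would move all LPS-changed genes back. Instead 658 genes moved further in the LPS direction, above the 216 that false calls at the threshold would allow (425 against 169.6 without LPS replicate 2, the lowest count on leaving out a library). The 216 does not cover an offset in scaling. Of the 658, 463 were lowered by both, and 322 of these had changed less than 2-fold with LPS, where a small offset could give such a call. The 463 were 343 with size factors by the DESeq2 method and 762 with library-size scaling. The 195 raised by both were 190 and 178. The lowered genes alone therefore do not decide against a weaker response. A candidate explanation is that the gas exposure reduced part of the LPS response and acted on other genes as well, while a shift of the response in time was not tested and argon is not separated from the handling that goes with it.

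Replicate 3 stood apart in all 3 groups in the same genes, with correlations of its deviations between groups of at least 0.72. Depth does not explain this, because the median correlation was 0.729 after every library was thinned to the smallest total. A few abundant genes do not either, since it was 0.737 outside the 500 most abundant. The values are consistent with a culture or preparation set shared by the replicates numbered 3 and another shared by numbers 1 and 2, which the labels do not record. A biological difference between the animals of the sets and a technical difference between preparations both stay open.

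More genes fell than rose with argon, at 63.2% of called genes. Low counts do not account for it, because 67.8% of the called genes with a mean of at least 10 CPM fell. Composition scaling may, since 42.5% fell when libraries were scaled by their totals, and the share was 52% with the replicate block. The mRNA content of the cells was not measured here, so which scaling is nearer to amounts per cell stays open.

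In the 10 ways of splitting 6 libraries into 3 and 3, the real split alone (1 of 10) reached its own count in each comparison, and 10 splits are too few for a share under 0.05. The real counts were 7260 for LPS against vehicle, 4327 for argon against LPS, 7181 for LPS plus argon against vehicle and 2467 genes moved back. The highest count in any other split was 0 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with up to 713, 1744 and 855 genes at an unadjusted p under 0.05 in the comparisons in that order. Each other split puts libraries of both groups on both sides, so the group difference enters the spread and lowers the count. The 0 was therefore largely fixed by the design and does not show how many calls chance would give. Of the splits, 4 part all 3 pairs of equal number, the real one included, and the others leave pairs together on a side.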
